A study of Mus musculus with 22 samples.

How the data were processed

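The deposited tables hold counts per gene symbol, raw read counts per the labels, for 32544 symbols in 22 samples, with the early lesion and the primary tumor experiment in separate tables. Per the submitters' processing notes, base calls were converted with bcl2fastq 2.17 and the genome was mm10. The aligner, counting tool, annotation and strand setting are not given in the sources used here, and raw reads were not used. Per the labels, RNA was prepared with RNeasy and libraries with NEBNext Ultra after oligo-dT selection. In the primary tumor table all 48 values of 1000000 or more end in 0, so the largest counts there carry 6 digits. A spreadsheet had turned 27 symbols into dates (0.0499 to 0.251% of counts, with 2 dates used more than once), and these were left as they stood. Of all symbols, 31394 were found in the GENCODE annotation used for coordinates and overlaps.

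Group, experiment, culture and replicate came from the labels, which call the replicates biological. Groups held 3 libraries each, except 2 for either macrophage group of the early lesion experiment. Co-culture was compared with mono-culture in early lesion cells, primary tumor cells and the macrophages of each experiment. The difference of the tumor cell responses and that of the macrophage responses were interaction terms over 4 groups, and early lesion and primary tumor cells were compared in mono-culture.

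Each comparison used edgeR 4.0.16 in R 4.3.3 on the counts (filterByExpr, TMM normalization, robust dispersion, quasi-likelihood F test, two-sided). P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Levels are TMM-normalized CPM of each fit. Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, and adjusted over the lists of a comparison. There were 31 lists and 1 list of 11 study genes, 516 entries in all, 515 of them measured, 3 under another symbol. The lists covered G2/M, DNA replication, dormancy, TGF-β ligands and targets, epithelial junctions, luminal and basal genes, mesenchymal transition, extracellular matrix and ErbB genes. They also covered alveolar, pan-macrophage, alternative activation and lipid-associated macrophage genes, interferon, MHC class I and II, inflammatory genes, glycolysis and hypoxia, fatty acid and cholesterol synthesis, stress response, Wnt and Notch. Markers of fibroblasts, neutrophils, endothelium, lymphocytes and lung epithelium and the mitochondrially encoded genes completed them. The lists, comparisons, tests, naming rule and other settings named next were chosen before the data were examined.

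A carry-over candidate had a mean CPM in the partner cells of the same co-culture at least 5 times that of the cells under test. Named were the 11 study genes (Tgfb1, Tgfb2, Tgfb3, Tgfbr1, Tgfbr2, Tgfbr3, Cdkn1b, Mki67, Cdh1, Erbb2 and Nr2f1), and the 6 rising and 6 falling genes with the largest change. Those needed a passing adjusted p, at least 10 CPM in the higher group, replicates that did not overlap, no candidate status and no provisional symbol. Also named were the 3 rising candidates with the largest change, and for each passing list the 3 members with the smallest adjusted p in its direction and 1 in the other. A gene that the rule names in the stage comparison is not reported here. For the TGF-β, dormancy, cell-cycle and interferon lists 2 members were named whatever the result. Where a group had 0 counts a bound against 3 counts is given, and with 1 to 3 counts a ratio with a counting interval.

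Other settings fixed in advance were RLE normalization, no filter, DESeq2 1.42.0, dispersion without robust estimation, a log2 change of at least 1, the replicate number as a block, all 4 groups of an experiment in 1 fit, leaving out carry-over candidates at 5 or 2 times, and leaving out each library. For lists they were an estimated correlation and fry, and for the stage comparison the difference relative to macrophages. Chosen after seeing the data were fits without mitochondrially encoded genes and Grip2, a share rule for tumor RNA, removal of a trend over transcript length, a fibroblast covariate and list tests leaving out each library.

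No pairing is given in the sources used here. Library residuals of the same number correlated at 0.461, 0.350 and 0.468 between co-cultured and mono-cultured primary tumor cells, and other pairs at -0.124 to -0.360, so the numbers were taken to pair them. In early lesion cells same numbers gave 0.287, 0.227 and 0.0612, under the limit of 0.1 for 1 number, and macrophages showed no pairing, at -0.0902 to 0.00418 in the primary tumor experiment.

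In a self-test, 200 genes were given known changes in counts simulated for each comparison. Of 1.5-fold, 2-fold and 4-fold changes, 63.1, 72.7 and 97.1% were recovered for early lesion cells, 51.4, 69.5 and 94.2% for primary tumor cells, 69.4, 75.0 and 90.0% for macrophages with early lesion cells, and 32.3, 64.1 and 93.0% for macrophages with primary tumor cells. The tumor difference gave 25.7, 58.5 and 67.7%, the macrophage difference 8.82, 47.6 and 79.7%, and the stage comparison 59.7, 71.2 and 98.2%. False calls were 5.45, 7.74, 13.3, 9.86, 7.41, 8.08 and 9.15% of calls in that order.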

Results

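Gene expression was measured by bulk RNA sequencing in 22 libraries of mouse cells in 8 groups. Mammary cells came from early lesions or from primary tumors of MMTV-HER2 mice, a transgenic breast cancer model driven by HER2. Alveolar macrophages, the resident phagocytes of the lung air spaces, came from wildtype FVB mice. Cells were grown on Matrigel, a basement membrane gel, alone or as a co-culture of mammary cells with macrophages for 7 days. The cell types of the co-cultures were then sorted by flow cytometry, with a gate that is not given in the sources used here. Each experiment held 4 groups of 3 libraries, except 2 for either macrophage group of the early lesion experiment. Each library had 19.7 to 43.7 M counts assigned to genes.

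Mitochondrially encoded genes took 2.86 to 3.53% of the counts in the 16 libraries of early lesion cells, the early lesion experiment's macrophages and primary tumor cells. In the primary tumor experiment's macrophages they took 69.3% ± 3.50 (SD, n = 3) in mono-culture and 76.7% ± 1.86 (n = 3) in co-culture. Grip2, a neuronal scaffold gene, took 12.9% of the counts of mono-cultured macrophage replicate 1 of that experiment and 1.85 to 2.60% in its other 5 macrophage libraries. It took 1.08 to 7.38% in the primary tumor cells and 0.0165 to 0.0739% in the early lesion experiment. All other genes together had 4.65 to 6.03 M counts in these 6 libraries, which limits the precision for low genes there. The composition plot shows the counts.

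**Figure D1:**
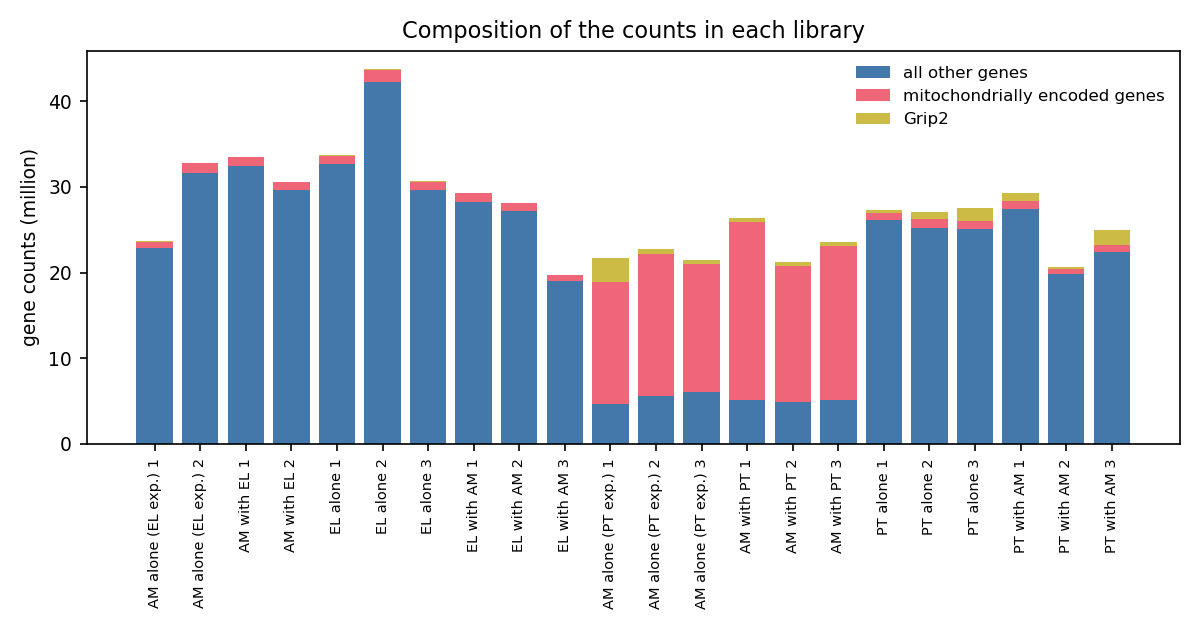
Counts of mitochondrially encoded genes, Grip2 and all other genes in each of the 22 libraries, 1 bar per library. The 6 macrophage libraries of the primary tumor experiment have 65.7 to 78.6% mitochondrially encoded counts, and the other 16 have 2.86 to 3.53%.

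Changes are log2 fold changes ± standard error, and levels are normalized counts per 1000000 (CPM) as mean ± SD. Adjusted p-values of single genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, and those of gene lists from camera with a preset correlation of 0.01. The p-values of single genes measure the spread between these libraries. Those of camera set a list's genes against all other genes, with the correlation between genes preset and not taken from these libraries. No call of a gene list in any of the 7 comparisons passed 0.05 with an estimated correlation. Transcripts of a gene far higher in the partner cells of the same co-culture could have been carried over with the sort. Genes at least 5 times higher in the partner are called carry-over candidates.

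The first comparison asked what co-culture with macrophages changed in early lesion cells (3 against 3 libraries). F5, coagulation factor V, rose by 2.13 ± 0.13 (37.1 ± 4.92 against 8.49 ± 1.02 CPM, edgeR quasi-likelihood adjusted p = 0.00394). The neutrophil chemokine Cxcl5 rose by 1.58 ± 0.18 (93.7 ± 8.65 against 31.4 ± 7.55 CPM). The monooxygenase Fmo2 rose by 1.37 ± 0.15, the potassium channel subunit Kcne3 by 1.37 ± 0.17, the cartilage matrix gene Chad by 1.47 ± 0.16 and the fibrillar collagen Col11a1 by 1.11 ± 0.09. Lgals7, a keratinocyte galectin, fell by 1.21 on the log2 scale (11.1 ± 1.24 against 25.9 ± 0.905 CPM). The amino acid transporter Slc6a15 changed by -1.59 ± 0.24, Clca3a2 by -0.95 ± 0.09, the protease Bace2 by -0.93 ± 0.14, the ectodysplasin receptor Eda2r by -0.89 ± 0.12 and the thioesterase Acot1 by -0.82 ± 0.08. F5, Chad and Lgals7 overlap other genes, so their counts are uncertain because the strand setting is not given in the sources used here. Cyba (0.44 ± 0.06) and Ctsd (0.31 ± 0.05) rose as candidates (partner ratios 6.96 and 5.35), which does not show carry-over.

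None of the 11 genes fixed for the question of TGF-β signaling and dormancy changed in the early lesion cells. Tgfb2, a ligand of the pathway, was at 17.7 ± 2.02 against 19.3 ± 0.629 CPM (-0.12 ± 0.09, edgeR quasi-likelihood adjusted p = 0.572). The receptor genes Tgfbr1, Tgfbr2 and Tgfbr3 had values of 0.02 ± 0.08, 0.13 ± 0.08 and -0.07 ± 0.13, and the ligands Tgfb1 and Tgfb3 of 0.04 ± 0.12 and -0.14 ± 0.07. The proliferation marker Mki67 was at 217 ± 42.3 against 254 ± 41.2 CPM (-0.23 ± 0.17) and the cell-cycle inhibitor Cdkn1b at 121 ± 6.97 against 110.1 ± 2.65 CPM (0.14 ± 0.05). The adhesion gene Cdh1 (0.14 ± 0.04), the receptor gene Erbb2 (0.17 ± 0.35) and the transcription factor Nr2f1 (0.26 ± 0.38) did not pass either. With the mean of the fibroblast markers as a covariate, chosen after seeing the data, Mki67 (-0.36), Erbb2 (0.39), Cdkn1b (0.16) and Cdh1 (0.14) passed.

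As groups, cell-cycle genes were lower. None of the 21 G2/M genes passed alone, nor adjusted over the list alone, but 0 of 21 lay above 0, the median was -0.29, and the list passed (camera adjusted p = 8.04e-05, and 0.930 with an estimated correlation). The kinesin Kif11 (-0.31 ± 0.17), the spindle factor Tpx2 (-0.31 ± 0.19) and the ubiquitin-conjugating enzyme gene Ube2c (-0.33 ± 0.16) are examples. DNA replication genes had a median of -0.27 over 21 members, 0 of them called over all genes or adjusted over the list alone (camera adjusted p = 2.32e-06, and 0.894 with an estimated correlation). The helicase subunit Mcm7 was at -0.26 ± 0.09, the nuclease Fen1 at -0.26 ± 0.09 and the licensing factor Cdc6 at -0.38 ± 0.14. The basal and myoepithelial list was lower (14 members, 0 called, 1 higher and 1 lower adjusted over the list alone, median -0.36, camera adjusted p = 0.0396, and 0.894 with an estimated correlation), with the basal keratin Krt5 at 287 ± 75.1 against 643 ± 99.8 CPM. Glycolysis and hypoxia genes were higher (19 members, 0 called, 4 adjusted over the list alone, median 0.15, camera adjusted p = 0.00244, and 0.894 with an estimated correlation). Among them Pfkp was at 0.37 ± 0.07, Pfkfb3 at 0.43 ± 0.08 and the aldolase gene Aldoa at 0.20 ± 0.04. Inflammatory cytokines and NF-κB targets were higher, with 1 of 20 called, Cxcl5, over all genes and adjusted over the list alone (camera adjusted p = 0.0454, and 0.944 with an estimated correlation). Cxcl1 was at 0.61 ± 0.15 there. MHC class II genes were higher with 0 of 6 called and 1 adjusted over the list alone (camera adjusted p = 0.0454, and 0.894 with an estimated correlation), with H2-Ab1 at 0.74 ± 0.18. Of these 6 genes, 3 were carry-over candidates, and the camera adjusted p was 0.223 without them.

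The dormancy list did not pass in early lesion cells (camera adjusted p = 0.624). Its member Cdkn1a, a cell-cycle inhibitor, was at 133 ± 11.6 against 180.2 ± 17.4 CPM (-0.44 ± 0.09), the 1 member lower adjusted over the list alone, and Btg1 at 0.30 ± 0.09. TGF-β target genes (0.972, with Klf10 at 0.13 ± 0.04 and Smad7 at -0.26 ± 0.10) and TGF-β ligands and receptors (0.972) did not pass camera, nor did interferon genes (0.972). The interferon list had a median of 0.02 against a mean of -0.05, with Ifi44 at 0.52 ± 0.15 and Bst2 at -0.32 ± 0.22. Test, median and mean also differed in sign for the luminal, ErbB, alveolar macrophage, alternative activation and cholesterol lists, none of which passed. Fibroblast markers had a median of 0.37 (camera adjusted p = 0.169, and 1.68e-05 with the replicate block). They were highest in co-cultured early lesion replicate 1, where Col1a1 had 1638 CPM against 502 to 933 in the other 5 early lesion libraries.

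In all, 55 genes were higher and 21 lower of 14891 tested, and 2213 had an unadjusted p under 0.05. Of all genes tested, 21.4% had replicates that did not overlap, where chance gives 10% for 3 against 3. Single libraries decided the count. Without co-cultured replicate 1 the calls were 1612, without co-cultured replicate 2 they were 26, and without co-cultured replicate 3 they were 1. Without mono-cultured replicates 1, 2 and 3 they were 10, 1 and 0. Each of the 14 called genes named here lost its call in at least 1 of these 6 fits. Without co-cultured replicate 1, Tpx2 (-0.55), Ube2c (-0.54), Kif11 (-0.50), Cdkn1a (-0.51) and Cdkn1b (0.19) passed, while 4 lists did not. Those were glycolysis and hypoxia (camera adjusted p = 0.185), inflammatory genes (0.768), MHC class II (0.313) and basal genes (0.0945). The basal list was also lost without mono-cultured replicate 3 (0.107), the inflammatory list without mono-cultured replicate 1 (0.211), and the MHC class II list without mono-cultured replicate 1 (0.211), mono-cultured replicate 2 (0.0909) or co-cultured replicate 3 (0.198). The G2/M and DNA replication lists passed with each library left out. Fibroblast markers passed upward without co-cultured replicate 2 (0.000530) or 3 (0.0265) or mono-cultured replicate 1 (0.0114), and mesenchymal genes without co-cultured replicate 2 (0.00231). With the replicate block neutrophil markers passed (0.0329) and MHC class II did not (0.187).

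The same question was asked of primary tumor cells (3 against 3 libraries). Apoe, a lipid carrier, rose by 1.58 ± 0.15 (78.7 ± 15.2 against 26.3 ± 2.76 CPM, edgeR quasi-likelihood adjusted p = 0.00969), and the chemokine Cxcl1 by 1.29 ± 0.16 (19.6 ± 4.07 against 8.03 ± 0.781 CPM). The matrix protein gene Olfml2a rose by 1.29 ± 0.23, the secretory cell transcription factor Bhlha15 by 1.19 ± 0.18 and Ndrg2 by 1.06 ± 0.19. Pcdhga8 rose by 1.69 ± 0.25, an uncertain value because the genes of its protocadherin cluster share exons. Has2, a hyaluronan synthase, changed by -1.53 ± 0.14 (7.57 ± 1.57 against 21.9 ± 1.04 CPM), the metalloprotease Adam12 by -1.29 ± 0.17 (68.6 ± 4.17 against 167 ± 37.7 CPM), tenascin C, Tnc, by -0.99 ± 0.11, the kinesin Kif26b by -1.70 ± 0.17, Gprin3 by -1.33 ± 0.22 and the chromatin protein Hmga2 by -0.96 ± 0.16. Has2 overlaps an antisense gene and is uncertain.

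The TGF-β receptor gene Tgfbr1 fell, at 42.2 ± 0.594 against 55.2 ± 4.18 CPM (-0.39 ± 0.07, edgeR quasi-likelihood adjusted p = 0.0393). TGF-β target genes were lower as a list (18 members, 2 lower, 1 higher and 5 lower adjusted over the list alone, median -0.10, camera adjusted p = 0.0261, and 0.562 with an estimated correlation). The repressors Skil (-0.43 ± 0.07) and Smad6 (-0.46 ± 0.08) fell, and Id3 was at -0.87 ± 0.17 without passing. The ligand and receptor list had 1 member lower (1 higher and 3 lower adjusted over the list alone) and did not pass (camera adjusted p = 0.326). Tgfb2 was at 32.7 ± 3.37 against 27.3 ± 5.42 CPM (0.26 ± 0.15), Tgfb1 at 0.07 ± 0.07, Tgfb3 at 0.18 ± 0.27, Tgfbr2 at 0.15 ± 0.08, Tgfbr3 at 0.42 ± 0.15 and Inhbb at 0.30 ± 0.06. Mki67 was at 110.3 ± 7.30 against 77.3 ± 29.7 CPM (0.51 ± 0.28), Cdkn1b at 0.15 ± 0.07, Erbb2 at 0.26 ± 0.11, Nr2f1 at -1.44 ± 0.37 and Cdh1 at 475 ± 37.2 against 475 ± 29.2 CPM, none of which passed. The dormancy list did not pass (camera adjusted p = 0.972, Gas1 at 0.31 ± 0.08).

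Cell-cycle lists pointed up in primary tumor cells. All 21 G2/M genes lay above 0 (median 0.37, 0 called, 0 adjusted over the list alone, camera adjusted p = 1.13e-06, and 0.574 with an estimated correlation), among them Nusap1 at 0.55 ± 0.18, Birc5 at 0.37 ± 0.13 and Aurkb at 0.59 ± 0.21. Of 21 DNA replication genes, 20 lay above 0 (median 0.35, 0 called, 1 adjusted over the list alone, camera adjusted p = 3.63e-06, and 0.574 with an estimated correlation), with E2f1 at 0.62 ± 0.14, Gins2 at 0.27 ± 0.10 and Mcm6 at 0.49 ± 0.18. All 19 glycolysis and hypoxia genes lay above 0 (median 0.36, camera adjusted p = 7.85e-07, and 0.574 with an estimated correlation). The phosphofructokinase gene Pfkp rose (225 ± 22.0 against 156 ± 6.36 CPM, 0.53 ± 0.08), the 1 call over all genes against 2 adjusted over the list alone, and Ldha was at 0.37 ± 0.08 and Bnip3 at 0.48 ± 0.15. MHC class I genes were higher (13 members, 2 called, 5 adjusted over the list alone, camera adjusted p = 0.0101, and 0.574 with an estimated correlation). The peptide transporter Tap2 rose by 0.35 ± 0.06 and H2-K1 by 0.36 ± 0.07, and Psmb9 was at 0.56 ± 0.18. Inflammatory genes were higher (13 members, 1 called, Cxcl1, and 3 adjusted over the list alone, camera adjusted p = 0.00302, and 0.574 with an estimated correlation), with Lcn2 at 0.28 ± 0.08 and Nfkbiz at 0.60 ± 0.17. Interferon response genes were lower, 1 of 16 above 0, with a median of -0.45, 0 called and 2 lower adjusted over the list alone (camera adjusted p = 4.52e-05, and 0.574 with an estimated correlation). Usp18 was at -1.90 ± 0.49, Irf9 at -0.40 ± 0.10 and Oas1a at -1.01 ± 0.30.

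Macrophage transcripts rose in the co-cultured primary tumor cells at low levels. Chil3, an alveolar macrophage gene, had 5.50 ± 0.840 against 0.0120 CPM, a ratio of 453 with a 95% counting interval of 80.8 to 17918. Ccl6 had 2.65 ± 0.200 against 0.0120 CPM, a ratio of 215 (38.2 to 8549). Such intervals cover counting error only. Lyz2 rose by 4.08 ± 0.70 and Pygl by 0.81 ± 0.08, and these 4 were carry-over candidates. At partner ratios of 619 (Lyz2) and 6.63 (Pygl) no single carried share gives both rises. Alveolar macrophage markers passed upward (6 members, 2 called, 2 adjusted over the list alone, median 0.02, camera adjusted p = 2.54e-09, and 0.0662 with an estimated correlation), with Plet1 at 0.24 ± 0.11. Pan-macrophage markers passed upward (12 members, 1 called, 3 adjusted over the list alone, camera adjusted p = 0.00245, and 0.574 with an estimated correlation), with the candidates Mrc1 at 1.49 ± 0.38 and Cybb at 0.57 ± 0.15. Alternative activation genes passed upward (6 members, 2 called, 4 adjusted over the list alone, camera adjusted p = 6.29e-08, and 0.0662 with an estimated correlation). Its arginase gene Arg1 rose by 1.21 ± 0.21 (5.70 ± 1.46 against 2.46 ± 0.157 CPM). Without carry-over candidates the camera adjusted p of these 3 lists was 0.882, with the direction turned, 0.862 and 0.292.

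In all, 89 genes were higher and 136 lower of 13506 tested, and 25.6% had replicates that did not overlap. The replicate numbers paired the primary tumor cell libraries, and with the number as a block 1430 genes were higher and 1411 lower, all 89 and 136 among them. Blocked calls also included Inhbb, Gas1, Id3, Nusap1, Birc5, Aurkb, E2f1, Gins2, Mcm6 and Ldha. Psmb9, Lcn2, Nfkbiz, Usp18, Irf9, Plet1, Mrc1 and Cybb passed too, all of them near the values above. With the block the luminal mammary list (camera adjusted p = 0.00610) and the extracellular matrix list (0.000562) also passed, and Mki67 and Cdkn1b did not. Without the block, leaving out co-cultured replicates 1, 2 and 3 gave 101, 4 and 26 calls, and leaving out mono-cultured replicates 1, 2 and 3 gave 101, 4 and 162. Of the 23 called genes named here, 21 lost their call in at least 1 of these 6 fits, the 2 others being Chil3 and Ccl6. The TGF-β target list was lost without co-cultured replicate 2 (0.0717) or mono-cultured replicate 2 (0.0715) or 3 (0.0703), MHC class I without co-cultured replicate 2 (0.123) or mono-cultured replicate 3 (0.0512), and the inflammatory list without co-cultured replicate 1 (0.0926). Gained were cholesterol synthesis without co-cultured replicate 1 (0.00206) or mono-cultured replicate 3 (0.0198), fibroblast markers without mono-cultured replicate 3 (0.00346), luminal genes without co-cultured replicate 3 (0.00720) and mitochondrially encoded genes without mono-cultured replicate 1 (0.0224).

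The difference between the 2 tumor cell responses was tested as an interaction (early lesion minus primary tumor response). Stage and experiment, each experiment with its own macrophages, are the same split, so this difference belongs to either or both. F5 (2.41 ± 0.35), Chad (2.08 ± 0.35), the interferon-induced Rtp4 (1.99 ± 0.30), the protease inhibitor Timp3 (1.04 ± 0.15) and the matrix protein gene Edil3 (0.96 ± 0.13) responded more positively in early lesion cells. Cpt1a, a carnitine palmitoyltransferase, stood at 136 ± 3.91 against 139 ± 6.37 CPM in early lesion cells and at 62.5 ± 4.54 against 118 ± 6.89 CPM in primary tumor cells (0.88 ± 0.09, edgeR quasi-likelihood adjusted p = 0.0049). Exoc3l4 (-1.35 ± 0.19), Fam174b (-1.16 ± 0.14), the Notch ligand Dll1 (-0.67 ± 0.11) and the peroxisomal protease Tysnd1 (-0.44 ± 0.07) responded more negatively. None of the 11 study genes passed without a block, with Mki67 at -0.74 ± 0.36, Tgfb2 at -0.38 ± 0.19, Tgfbr1 at 0.40 ± 0.10 and Cdkn1b at -0.01 ± 0.09. With the replicate block Tgfbr1 (0.40, adjusted p = 0.0103), Tgfb3 (-0.32, 0.0274) and Nr2f1 (1.55, 0.0477) passed. In all 15 genes were higher and 6 lower of 15284 tested.

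The G2/M list had a median difference of -0.67, with 0 of 21 above 0 and 0 called or adjusted over the list alone (camera adjusted p = 1.65e-11, and 0.539 with an estimated correlation). The DNA replication list had a median of -0.70, with 0 called and 1 lower adjusted over the list alone (camera adjusted p = 3.75e-13, and 0.539 with an estimated correlation). Glycolysis and hypoxia genes differed downward (median -0.24, camera adjusted p = 0.0185, and 0.615 with an estimated correlation). Interferon genes (median 0.45, 1 adjusted over the list alone, camera adjusted p = 0.00348, and 0.615 with an estimated correlation) and TGF-β targets differed upward (median 0.17, 4 adjusted over the list alone, camera adjusted p = 0.0253, and 0.385 with an estimated correlation), with Skil at 0.60 ± 0.11. So did neutrophil markers (median 1.16, 2 adjusted over the list alone, camera adjusted p = 0.0357, and 0.385 with an estimated correlation) and fibroblast markers (median 0.73, camera adjusted p = 0.0452, and 0.812 with an estimated correlation). No member of these 7 lists was called over all genes.

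Leaving out co-cultured early lesion replicate 1 gave 184 genes with a different response, co-cultured primary tumor replicate 1 gave 54, mono-cultured primary tumor replicate 3 gave 47 and mono-cultured primary tumor replicate 2 gave 9. Leaving out 1 of 5 other libraries gave 12 to 14. Of the 10 named calls, Fam174b, Edil3 and Cpt1a kept theirs with each library left out. With the replicate number as a block 529 genes were higher and 600 lower, and the luminal mammary list passed (camera adjusted p = 0.0375). Without co-cultured early lesion replicate 1 the lists of fibroblast markers (0.574), interferon genes (0.125), neutrophil markers (0.125) and TGF-β targets (0.205) did not pass. Without mono-cultured primary tumor replicate 3 interferon genes (0.0842), neutrophil markers (0.0842) and TGF-β targets (0.0778) did not. Glycolysis was lost without co-cultured primary tumor replicate 3 (0.222) and neutrophil markers without co-cultured primary tumor replicate 1 (0.0526). Fibroblast markers were lost too without mono-cultured early lesion replicate 2 (0.214), co-cultured primary tumor replicates 1 (0.0526) or 2 (0.0776), or mono-cultured primary tumor replicates 1 (0.0791) or 2 (0.116). Among lists gained, MHC class I passed in 5 of the 12 fits, with co-cultured primary tumor replicate 3 (0.0163) or 1 (0.0294), mono-cultured primary tumor replicate 2 (0.0237), co-cultured early lesion replicate 3 (0.0274) or mono-cultured early lesion replicate 1 (0.0330) left out. The matrix list passed without co-cultured early lesion replicate 1 (0.00385), alveolar macrophage markers without co-cultured (0.0274) or mono-cultured early lesion replicate 3 (0.00122) or co-cultured primary tumor replicate 3 (0.0418), and luminal genes without co-cultured early lesion replicate 2 (0.0460) or co-cultured primary tumor replicate 3 (0.0384). Notch genes passed without co-cultured primary tumor replicate 3 (0.0418), cholesterol (0.0144) and stress response genes (0.00907) without co-cultured primary tumor replicate 1, alternative activation genes without mono-cultured early lesion replicate 3 (0.0213) and mitochondrially encoded genes without mono-cultured primary tumor replicate 1 (0.00270).

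Over 13083 genes the 2 tumor cell responses had a correlation across genes of r = 0.188 (Spearman rho = 0.137), and genes are not independent replicates. The 7 genes higher in both were Ly6d (1.11 and 1.03), Glul (0.95 and 0.71), Arhgef10 (0.71 and 0.90), Ckmt1 (0.67 and 0.68), H6pd (0.66 and 0.61), Crip1 (0.62 and 0.63) and Txnip (0.55 and 0.85). Acot1 (-0.82 and -0.71) and Aqp9 (-0.74 and -1.36) were lower in both. Independent lists would share 0.356 higher and 0.217 lower genes, and 1 gene was called in opposite directions. These genes were listed after their values were seen.

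**Figure D2:**
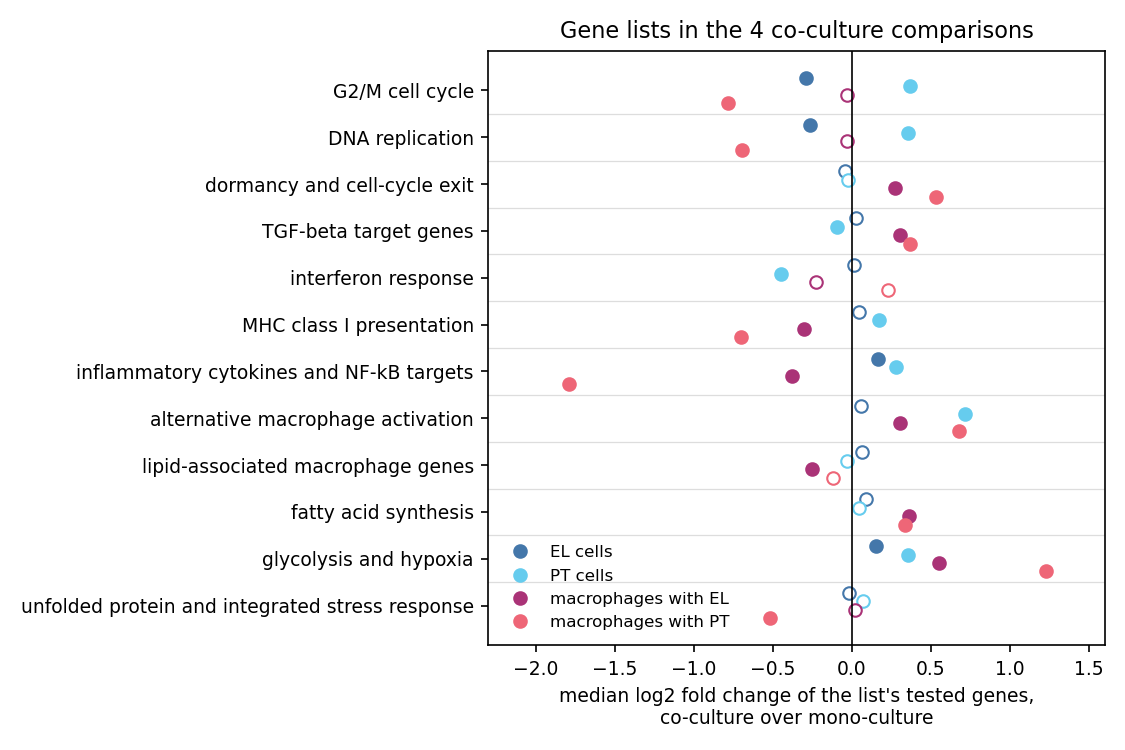
Median log2 fold change of 12 gene lists in the 4 co-culture comparisons, filled where the list passed camera with a preset correlation of 0.01 and open where it did not. The G2/M list lies at -0.29 in early lesion cells and at 0.37 in primary tumor cells, and glycolysis and hypoxia genes lie at 1.23 in macrophages with primary tumor cells.

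In macrophages co-cultured with early lesion cells (2 against 2 libraries), the transglutaminase F13a1 rose by 6.35 ± 0.41 (14.8 ± 5.24 against 0.177 ± 0.0106 CPM, edgeR quasi-likelihood adjusted p = 5.86e-05). The glycoprotein Lrg1 rose by 4.77 ± 0.13, fibronectin, Fn1, by 3.93 ± 0.22 (1229 ± 305 against 80.5 ± 3.25 CPM), the proteoglycan Vcan by 3.17 ± 0.22, the calcium channel Cacna1d by 3.08 ± 0.20 and the AP-1 factor Fosb by 2.84 ± 0.28. Clec4e, a receptor for mycobacterial glycolipid, changed by -2.65 ± 0.08 (21.05 ± 0.505 against 132 ± 10.8 CPM) and the neutrophil chemokine Cxcl3 by -2.53 ± 0.07 (20.5 ± 0.253 against 118 ± 3.07 CPM). Bex1 (-3.17 ± 0.12), the cysteine dioxygenase Cdo1 (-2.57 ± 0.11), Sox7 (-2.56 ± 0.18) and Ctla2b (-2.56 ± 0.13) also fell.

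TGF-β target genes rose as a list in these macrophages, 10 of 18 higher and 2 lower (11 and 2 adjusted over the list alone, camera adjusted p = 1.49e-07, and 0.5003 with an estimated correlation). Tgfbi, a secreted TGF-β-induced protein, rose by 2.41 ± 0.10 (731 ± 64.6 against 138 ± 18.3 CPM) and Id1 by 1.37 ± 0.11, and the repressor Tgif1 fell by 0.50. Pmepa1 rose by 0.73 ± 0.10 as a carry-over candidate. Of the ligand and receptor list, 5 of 20 rose (6 adjusted over the list alone, camera adjusted p = 0.00747, and 0.520 with an estimated correlation). Tgfb3 (3.86 ± 0.45), Inhbb (4.72 ± 0.44) and Ltbp3 (0.58 ± 0.07) were carry-over candidates, as were 12 of the 20, and the list's adjusted p was 0.483 without them. Tgfb3 also overlaps another gene. Tgfb1 (0.16 ± 0.06), Tgfbr1 (0.09 ± 0.08), Tgfbr2 (0.08 ± 0.08) and Tgfbr3 (-0.21 ± 0.36) did not pass, and Tgfb2 (0.207 against 0.197 CPM) and Nr2f1 (0.292 against 0.301 CPM) were too low to test. The dormancy list passed upward with 3 higher and 1 lower of 18 (4 and 1 adjusted over the list alone, camera adjusted p = 0.0107, and 0.5003 with an estimated correlation). Cdkn1a rose by 1.09 ± 0.09 (85.5 ± 6.29 against 40.3 ± 5.15 CPM) and Bhlhe41 fell by 0.54. Thbs1 (3.53 ± 0.21) and Sox9 (1.96 ± 0.44) rose as candidates, but partner ratios of 11.4 and 159 imply different tumor RNA shares. Without candidates that list's adjusted p was 0.460. Cdkn1b (0.02 ± 0.07) and Mki67 (719 ± 68.0 against 763 ± 64.0 CPM) did not pass, nor did the G2/M list (camera adjusted p = 0.682, with Ube2c at -0.21 ± 0.07 and Cdc20 at -0.25 ± 0.08). In the DNA replication list (0.615) E2f1 (-0.29 ± 0.07) and Cdt1 (-0.22 ± 0.07) fell, 2 of 21 members (1 adjusted over the list alone).

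Inflammatory genes fell, 10 of 20 lower and 3 higher (10 and 4 adjusted over the list alone, camera adjusted p = 7.32e-10, and 0.5003 with an estimated correlation). The NF-κB genes Tnfaip3 (-1.53 ± 0.09) and Relb (-1.59 ± 0.10) fell and Nos2 rose by 3.70 ± 0.54. MHC class I genes fell in 6 of 13 cases (6 adjusted over the list alone, camera adjusted p = 5.45e-05, and 0.5003 with an estimated correlation), with B2m at 771 ± 16.4 against 1281 ± 14.3 CPM, H2-K1 at -0.92 ± 0.08 and Tapbp at -0.52 ± 0.06. In the lipid-associated list 10 of 18 fell and 4 rose (10 and 4 adjusted over the list alone, camera adjusted p = 0.0299, and 0.520 with an estimated correlation). The lipase Lpl (416 ± 1.49 against 1265 ± 76.5 CPM), the fatty acid transporter Cd36 (-1.14 ± 0.07) and Fabp4 (-1.01 ± 0.08) fell, and osteopontin, Spp1, rose by 1.99 ± 0.10 as a carry-over candidate. Alternative activation genes passed upward with 3 higher and 3 lower of 12 (4 and 3 adjusted over the list alone, camera adjusted p = 0.0314, and 0.5003 with an estimated correlation). The interleukin 4 receptor gene Il4ra rose by 1.35 ± 0.07 (464 ± 32.1 against 182 ± 0.174 CPM), the mannose receptor Mrc1 by 0.75 ± 0.10 and Cd200r1 by 0.32 ± 0.07, and Socs2 fell by 0.24. Glycolysis and hypoxia genes rose in 10 of 19 cases (14 adjusted over the list alone, camera adjusted p = 1.96e-08, and 0.5003 with an estimated correlation), with Pfkfb3 at 1.30 ± 0.10, Pdk1 at 0.69 ± 0.09 and Pkm at 0.51 ± 0.08. Fatty acid synthesis genes rose in 6 of 12 cases and fell in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.000843, and 0.5003 with an estimated correlation). Scd1 rose by 1.51 ± 0.12 as a carry-over candidate, Elovl6 by 0.70 ± 0.09 and Scd2 by 0.56 ± 0.08, and Me1 fell by 0.94. Mitochondrially encoded genes were lower in 6 of 9 cases (7 adjusted over the list alone, camera adjusted p = 0.0133, and 0.520 with an estimated correlation), with mt-Nd1 at -0.45 ± 0.07. Interferon genes did not pass (camera adjusted p = 0.105), with 2 higher and 4 lower (2 and 6 adjusted over the list alone), among them Bst2 (-0.68 ± 0.09) and Gbp2 (-0.52 ± 0.09). Alveolar macrophage markers did not pass either (0.765), with 4 higher and 5 lower.

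Transcripts of mammary epithelium rose in the same macrophages, mostly as carry-over candidates. Epithelial junction genes rose in 12 of 18 cases (13 adjusted over the list alone, camera adjusted p = 3.77e-10, and 0.5003 with an estimated correlation), 14 of the 18 being candidates. Epcam rose by 2.72 ± 0.21 and desmoplakin, Dsp, by 3.85 ± 0.31. Cdh1 rose from 44.2 ± 2.84 to 112 ± 10.3 CPM and Erbb2 from 18.0 ± 0.0164 to 47.7 ± 5.94 CPM. Luminal genes rose in 7 of 13 cases and fell in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 1.85e-07, and 0.5003 with an estimated correlation), 11 of them candidates. The keratin Krt18 rose by 5.93 ± 0.45 and the casein Csn3 by 4.81 ± 0.35, and Krt8 had a ratio of 121 (95% counting interval 41.1 to 589). Csn2 fell by 1.48, but in mono-culture it was higher in macrophages (341 CPM) than in early lesion cells (20.8 CPM). Basal genes rose in 5 of 10 cases (6 adjusted over the list alone, camera adjusted p = 0.000843, and 0.520 with an estimated correlation), 9 of them candidates, with Krt14 at 4.34 ± 0.43, Krt5 at 2.16 ± 0.44 and Trp63 at a ratio of 15.8 (5.14 to 79.2). Extracellular matrix genes rose in 7 of 19 cases (8 adjusted over the list alone, camera adjusted p = 1.49e-07, and 0.5003 with an estimated correlation), 17 of them candidates, with Lama5 at 2.60 ± 0.33 and Lamb3 at 1.91 ± 0.31. ErbB genes rose in 2 of 10 cases (3 adjusted over the list alone, camera adjusted p = 0.0216, and 0.520 with an estimated correlation), Erbb2 and Dusp6 (0.39 ± 0.07). Of the rising genes named in this paragraph, all but Dusp6 and Cxcr2 were candidates. Neutrophil markers passed upward with 2 higher and 1 lower of 4 (2 and 1 adjusted over the list alone, camera adjusted p = 0.00563, and 0.5003 with an estimated correlation). The chemokine receptor Cxcr2 rose by 1.30 ± 0.10, Mmp9 by 5.41 ± 0.47, and S100a8 fell by 0.44. Without carry-over candidates the junction (0.560), ErbB (0.483) and neutrophil (0.189) lists did not pass, and the luminal, basal and matrix lists, mostly candidates, were not shown to. The 3 rising candidates with the largest change were Lcn2 (5.22 ± 0.40), Csn1s1 (4.63 ± 0.35) and Chil1 (4.35 ± 0.21).

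With early lesion cells 1279 macrophage genes were higher and 1289 lower of 14032 tested, and 275 and 78 of them were carry-over candidates. Leaving out single libraries, with the lone sample assumed to vary like the other group, gave 1793 to 2945 calls. It ended the calls of E2f1 (without mono-cultured replicate 1 or co-cultured replicate 1), Cdt1 (these or mono-cultured replicate 2), Krt5 and mt-Atp6 (co-cultured replicate 1) and Socs2 (mono-cultured replicate 1 or either co-cultured replicate). The lipid-associated list did not pass without mono-cultured replicate 1 or either co-cultured replicate, or with the replicate block (0.213). The dormancy and ErbB lists did not pass without mono-cultured replicate 2. Mesenchymal genes passed without mono-cultured replicate 1 or either co-cultured replicate, or with the block (0.00187). The Notch pathway passed without either mono-cultured replicate or co-cultured replicate 2, or with the block (0.0405). Fibroblast markers passed without mono-cultured replicate 1 or with the block (0.0325), and interferon genes without mono-cultured replicate 2.

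In macrophages co-cultured with primary tumor cells (3 against 3 libraries), F13a1 rose by 7.16 ± 0.28 (10.2 ± 0.940 against 0.0684 ± 0.0301 CPM, edgeR quasi-likelihood adjusted p = 6.74e-09). Hypoxia-induced Egln3 rose by 5.30 ± 0.36 (26.8 ± 6.75 against 0.644 ± 0.423 CPM) and Bnip3 by 3.52 ± 0.14 (97.8 ± 13.6 against 8.44 ± 1.44 CPM). The collagenase Mmp8 rose by 3.96 ± 0.23, Tgfbi by 3.85 ± 0.21 and Cxcr2 by 3.34 ± 0.34. Clec4e changed by -4.93 ± 0.28 (0.742 ± 0.0560 against 22.9 ± 6.66 CPM), complement factor B, Cfb, by -3.12 ± 0.14, the chemokine Ccl3 by -2.75 ± 0.15 and the phagosomal metal transporter Slc11a1 by -2.62 ± 0.21. Arfgef3 (-3.24 ± 0.14) and Zc3h12c (-2.75 ± 0.16) fell as well. These libraries are those with 65.7 to 78.6% mitochondrially encoded counts.

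Glycolysis and hypoxia genes rose in 16 of 18 cases (16 adjusted over the list alone, median 1.23, camera adjusted p = 1.5e-27, and 0.0982 with an estimated correlation), with Pdk1 at 2.48 ± 0.10 and Pfkfb3 at 2.54 ± 0.13. Proliferation genes fell. Mki67 changed by -1.30 ± 0.10 (53.1 ± 5.56 against 131 ± 8.05 CPM), and 18 of 21 G2/M genes fell (20 adjusted over the list alone, median -0.78, camera adjusted p = 2.2e-09, and 0.226 with an estimated correlation), Ccnb1 by 1.05 and Tpx2 by 1.01. Of 21 DNA replication genes, 16 fell (18 adjusted over the list alone, median -0.69, camera adjusted p = 1.63e-08, and 0.305 with an estimated correlation), the polymerase genes Pole by 1.94 and Pola1 by 1.28, and Cdt1 by 0.79. The dormancy list passed upward with 5 of 14 higher (5 adjusted over the list alone, camera adjusted p = 0.019, and 0.172 with an estimated correlation). Cdkn1b rose by 0.69 ± 0.11 (22.9 ± 1.35 against 14.2 ± 1.12 CPM), Cdkn1a by 1.10 ± 0.12 and the antiproliferative Btg1 by 0.72 ± 0.09. TGF-β targets passed upward with 8 higher and 2 lower of 16 (9 and 2 adjusted over the list alone, camera adjusted p = 0.00141, and 0.158 with an estimated correlation), Klf10 by 0.85 ± 0.09 and Id1 by 1.79 ± 0.20, with Id2 lower by -1.09 ± 0.11. Ligands and receptors did not pass (camera adjusted p = 0.690, 4 higher and 2 lower). Inhba fell by 2.33, Tgfb3 rose by 3.39 ± 0.64 as a candidate, and Inhbb, another, was at least 29.4-fold higher, against a floor of 3 counts over the mono-cultured group. Tgfb1 (0.09 ± 0.12), Tgfbr1 (-0.17 ± 0.16) and Tgfbr2 (0.08 ± 0.11) did not pass, and Tgfb2, Tgfbr3 and Nr2f1 were too low to test.

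Inflammatory genes fell in 10 of 13 cases and rose in 1 (10 and 1 adjusted over the list alone, median -1.79, camera adjusted p = 9.73e-10, and 0.0942 with an estimated correlation), Tnfaip3 by 1.79 and Relb by 2.11. MHC class I genes fell in 7 of 12 cases (8 adjusted over the list alone, camera adjusted p = 0.00404, and 0.172 with an estimated correlation), with B2m at 135 ± 10.2 against 279 ± 69.8 CPM, H2-K1 at -0.89 ± 0.12 and Nlrc5 at -1.92 ± 0.37. Stress response genes fell in 7 of 14 cases and rose in 1 (9 and 1 adjusted over the list alone, camera adjusted p = 0.0239, and 0.307 with an estimated correlation), with the chaperone Hspa5 at -0.73 ± 0.10, Atf3 at -1.27 ± 0.18, Calr at -0.69 ± 0.12 and Xbp1 at 0.77 ± 0.09. Alveolar macrophage markers rose in 11 of 19 cases and fell in 3 (11 and 3 adjusted over the list alone, camera adjusted p = 0.000444, and 0.307 with an estimated correlation). The carbonic anhydrase Car4 rose by 1.78 ± 0.12, the lipid droplet gene Cidec by 2.51 ± 0.20 and Fabp1 by 2.89 ± 0.25, and the integrin Itgax fell by 1.52. Alternative activation genes rose in 4 of 6 cases (4 adjusted over the list alone, camera adjusted p = 0.0284, and 0.465 with an estimated correlation). Arg1 rose by 4.74 ± 0.47, Il4ra by 1.18 ± 0.20 and Chil3 from 1702 ± 286 to 2948 ± 371 CPM. Fatty acid synthesis genes rose in 4 of 11 cases and fell in 2 (5 and 2 adjusted over the list alone, camera adjusted p = 0.00246, and 0.158 with an estimated correlation), 10 of them candidates, with Scd1 (2.75 ± 0.15) and Scd2 (1.16 ± 0.11) among them, Acly at 1.01 ± 0.08 and Acaca at -0.32 ± 0.09. The interferon list did not pass (camera adjusted p = 0.454), with Irf9 at 0.91 ± 0.17 and Bst2 at -0.96 ± 0.20 among 3 higher and 1 lower, and pan-macrophage genes (0.0896) did not pass. Nor did mitochondrially encoded genes (0.0637, and 0.0449 with the replicate block), though 8 of 9 were higher, also adjusted over the list alone (median 0.54).

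Epithelial transcripts rose here too, and every gene named in this paragraph was a candidate by CPM of the whole library. Luminal genes rose in 7 of 9 cases (7 adjusted over the list alone, camera adjusted p = 7.09e-07, and 0.0982 with an estimated correlation), 8 of them candidates, with Krt19 at 2.65 ± 0.21, Csn3 at 6.63 ± 0.57 and Csn1s1 at 6.21 ± 0.72. Epithelial junction genes rose in 5 of 13 cases, all 13 being candidates (6 adjusted over the list alone, camera adjusted p = 0.00198, and 0.307 with an estimated correlation). Dsp rose by 2.28 ± 0.27, Epcam had a ratio of 26.9 (8.92 to 133) and Pkp1 of 66.9 (11.6 to 2677), while Cdh1 was at 3.997 ± 0.861 against 3.02 ± 1.02 CPM without passing. Basal genes rose in 1 of 4 cases (1 adjusted over the list alone, camera adjusted p = 0.0341, and 0.307 with an estimated correlation), Krt14 with a ratio of 125 (34.2 to 1037). Itga6 was at 0.39 ± 0.16 and Tagln at 0.97 ± 0.47. ErbB genes rose in 3 of 4 cases, all 4 being candidates (4 adjusted over the list alone, camera adjusted p = 3.44e-05, and 0.158 with an estimated correlation), Erbb2 from 1.72 ± 0.0993 to 18.8 ± 3.29 CPM, Dusp6 by 0.68 ± 0.10 and Egfr by 1.26 ± 0.40. Extracellular matrix genes rose in 4 of 15 cases, all 15 being candidates (4 adjusted over the list alone, camera adjusted p = 0.0341, and 0.451 with an estimated correlation), with Fn1 at 2.86 ± 0.25, Lama5 at 2.69 ± 0.42 and Lamb1 at 1.47 ± 0.33. The rising candidates with the largest change were Lrg1 (6.52 ± 0.31), Lcn2 (6.30 ± 0.53) and Igfbp5 (4.63 ± 0.85).

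With primary tumor cells 1759 macrophage genes were higher and 1644 lower of 11121 tested, and 45.0% had replicates that did not overlap. Carry-over candidates were 676 of the higher and 831 of the lower genes, and without candidates 1035 were higher and 901 lower of 5088 tested. Mitochondrially encoded transcripts fill these libraries. They lower the partner ratio of primary tumor cells, where leaving them and Grip2 out gave 704 candidates instead of 245, Bnip3 included. They raise the ratio of partner to macrophage CPM here. On CPM without them and Grip2, chosen after seeing the data, 953 genes were candidates instead of 6033, 142 of the higher and 139 of the lower calls, and Lrg1, Krt19, Tagln, Dusp6, Fn1, Cdkn1a, Xbp1 and Irf9 were none. Without the 6033 the lists of dormancy (0.102), alternative activation (0.0896), MHC class I (0.171) and stress response (0.135) did not pass, but carry-over adds transcripts and would not lower the last 2. The luminal, junction, basal, ErbB, matrix and fatty acid lists, mostly candidates, were not shown to pass. Without co-cultured replicate 3 the calls were 1303 higher and 1074 lower. Igfbp5 was lost without any 1 of the 3 mono-cultured replicates, Egfr without mono-cultured replicate 2 or 3 or co-cultured replicate 1 or 3, and Acaca without mono-cultured replicate 2 or co-cultured replicate 2 or 3. The alternative activation list was lost without mono-cultured replicates 1 (0.0629) or 3 (0.109) or co-cultured replicates 2 (0.0682) or 3 (0.0603). The basal list was lost without mono-cultured replicate 3 (0.137), and the matrix list without mono-cultured replicates 2 (0.0576) or 3 (0.0576). Mesenchymal genes passed without co-cultured replicate 1 (0.0337), pan-macrophage genes without mono-cultured replicate 3 (0.0113) and mitochondrially encoded genes without co-cultured replicate 2 (0.0186) or mono-cultured replicate 1 (0.0334).

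The macrophage responses to the 2 partners were correlated across 10977 genes (r = 0.587, Spearman rho = 0.406, genes not being independent replicates). In both, 599 genes were higher and 604 lower, where independent lists would share 172 and 181, and 84 were called in opposite directions against 355 by chance. Without carry-over candidates 387 and 339 were shared, against 130.1 and 105 by chance. The plot of both responses shows them gene by gene.

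**Figure D3:**
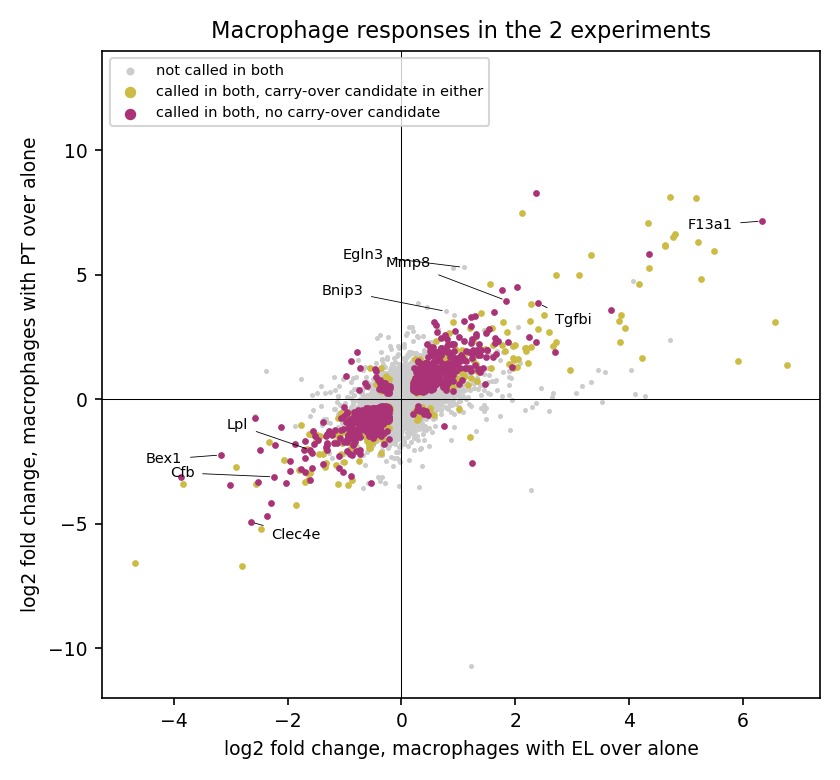
Log2 fold change of each gene tested in macrophages with early lesion cells (horizontal axis) and with primary tumor cells (vertical axis), with genes called in both in purple, carry-over candidates in yellow and genes not called in both in gray. F13a1 lies at 6.35 and 7.16, and Clec4e at -2.65 and -4.93.

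The difference between these responses was tested as an interaction (response to early lesion minus response to primary tumor cells). Egln3 (-4.19 ± 0.59, edgeR quasi-likelihood adjusted p = 0.00447), Bnip3 (-2.72 ± 0.25), Fabp1 (-2.74 ± 0.30), Rnase4 (-2.54 ± 0.27), the apolipoprotein Apoc1 (-2.52 ± 0.34) and Cyp2ab1 (-2.46 ± 0.37) responded more negatively with early lesion cells. The metalloprotease Adam8 (3.84 ± 0.25), the interleukin 7 receptor Il7r (2.84 ± 0.26), the integrin Itgam (2.53 ± 0.22), the chemokine Cxcl2 (2.41 ± 0.61), Clec4e (2.30 ± 0.36) and the histone Hist2h3c2 (2.54 ± 0.71) responded more positively. Of the study genes, Mki67 (1.22 ± 0.15), Cdkn1b (-0.66 ± 0.14), Erbb2 (-2.04 ± 0.22) and Cdh1 (0.93 ± 0.28) differed. Erbb2 and Cdh1 were candidates, and the tumor RNA shares implied by Erbb2 (0.591 and 1.22%) lay near the marker medians (0.542 and 0.685%), so its value need not be a macrophage response. Mki67 was at 271 ± 24.8 against 290.1 ± 26.0 CPM with early lesion cells and at 101 ± 10.5 against 252 ± 14.2 CPM with primary tumor cells in this fit.

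Glycolysis and hypoxia genes differed downward in 11 of 19 cases (13 adjusted over the list alone, median -0.66, camera adjusted p = 1.41e-12, and 0.234 with an estimated correlation), with Pdk1 at -1.77 ± 0.15 and Pgk1 at -1.73 ± 0.23. G2/M genes differed upward in 14 of 21 cases (17 adjusted over the list alone, median 0.79, camera adjusted p = 8.16e-14, and 0.234 with an estimated correlation), with Tpx2 at 1.01 ± 0.18 and Prc1 at 1.13 ± 0.20. DNA replication genes did so in 13 of 21 cases (17 adjusted over the list alone, median 0.78, camera adjusted p = 1.68e-13, and 0.268 with an estimated correlation), with Pole at 1.92 ± 0.19, Pola1 at 1.53 ± 0.20 and Mcm4 at 0.78 ± 0.16. Inflammatory genes differed upward in 6 of 20 cases (8 and 1 lower adjusted over the list alone, median 0.74, camera adjusted p = 0.00164, and 0.234 with an estimated correlation), Ccl3 by 1.20 ± 0.21, Icam1 by 1.14 ± 0.21 and Il1a by 0.67 ± 0.16. Alveolar macrophage markers differed downward in 7 of 19 cases and upward in 1 (8 and 2 adjusted over the list alone, median -0.42, camera adjusted p = 0.000258, and 0.355 with an estimated correlation), with Krt79 at -1.64 ± 0.18, Cidec at -2.21 ± 0.25 and Itgax at 0.81 ± 0.20. Stress response genes differed upward in 4 of 15 cases and downward in 1 (5 and 1 adjusted over the list alone, median 0.51, camera adjusted p = 0.0239, and 0.355 with an estimated correlation), with Hspa5 at 0.91 ± 0.14, Calr at 0.71 ± 0.18, Pdia4 at 0.76 ± 0.21 and Xbp1 at -0.61 ± 0.13. That list's adjusted p was 0.475 without carry-over candidates and 0.0665 without mitochondrially encoded genes and Grip2. Mitochondrially encoded genes differed downward in 8 of 9 cases (9 adjusted over the list alone, median -0.75, camera adjusted p = 0.000258, and 0.582 with an estimated correlation). The TGF-β and dormancy lists did not pass, with Tgfbi at -1.43 ± 0.27, Btg1 at -0.68 ± 0.14, Inhba at 2.16 ± 0.24, Acvr1 at 0.71 ± 0.22 and the candidates Ctgf at 4.08 ± 0.75 and Thbs1 at 3.67 ± 0.37 called, nor did interferon genes, with Ifi27l2a at -1.55 ± 0.27 and Gbp3 at -1.11 ± 0.28 called. Without carry-over candidates the dormancy list passed (0.0261).

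In all 720 genes were higher and 783 lower of 13727 tested, and without carry-over candidates 422 and 424 of 6349. Each experiment held 1 partner only, so partner and experiment cannot be told apart in this difference. Leaving out 1 library moved the total beyond 1.5 times in 4 cases, those of the early lesion experiment's macrophages. Without co-cultured replicate 3 or mono-cultured replicate 2 of the primary tumor experiment it was 1004 (459 higher) or 1075. Cdh1 lost its call in 8 of the 10 fits that left out 1 library and with the trend over transcript length removed (adjusted p = 0.0833). Hist2h3c2, Cxcl2, Acvr1, Itgax, Gbp3, Il1a, Calr, Pdia4 and Xbp1 each lost theirs in at least 1. The stress response list was lost without mono-cultured replicate 2 of the early lesion experiment (0.0503) or co-cultured replicate 3 of the primary tumor experiment (0.0793). The matrix list passed without mono-cultured replicate 1 (0.000151) or co-cultured replicate 2 (0.0262) of the early lesion experiment.

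Early lesion and primary tumor cells were also compared in mono-culture (3 against 3 libraries). Stage and experiment are the same split there, so the difference belongs to either or both. Fibroblast markers were higher in the early lesion libraries, 10 of 12 (10 adjusted over the list alone, median 3.51, camera adjusted p = 0.000668, and 0.764 with an estimated correlation), with decorin, Dcn, at 45.9 ± 12.8 against 1.53 ± 0.0670 CPM (4.90 ± 0.28), Lum at 5.04 ± 0.38 and Pdgfrb at 4.17 ± 0.29. Extracellular matrix genes were higher in 18 of 20 cases and lower in 1 (18 and 1 adjusted over the list alone, median 1.76, camera adjusted p = 2.82e-06, and 0.764 with an estimated correlation), with Lama5 at 1.25 ± 0.09, Lamb3 at 0.88 ± 0.05 and Fn1 at -0.91 ± 0.23. Mesenchymal genes were higher in 14 of 19 cases and lower in 3 (14 and 3 adjusted over the list alone, camera adjusted p = 0.00409, and 0.764 with an estimated correlation), with Tnc at 759.9 ± 145 against 153 ± 17.3 CPM, Prrx1 at 3.51 ± 0.19, Cdh11 at 2.42 ± 0.20 and Cdh2 at -1.51 ± 0.31. Inflammatory genes were higher in 16 of 18 cases and lower in 1 (16 and 1 adjusted over the list alone, median 2.57, camera adjusted p = 1.68e-06, and 0.764 with an estimated correlation), with Cxcl1 at 3.04 ± 0.18, Tnf at 2.79 ± 0.20, Nfkbiz at 2.36 ± 0.10 and Lcn2 at -1.38 ± 0.14.

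Lipid synthesis genes were lower in early lesion cells. Cholesterol synthesis genes were lower in 15 of 20 cases (15 adjusted over the list alone, camera adjusted p = 0.00794, and 0.853 with an estimated correlation), with Idi1 at -1.07 ± 0.07, Insig1 at -1.49 ± 0.12 and Stard4 at -0.71 ± 0.09. Fatty acid synthesis genes were lower in 9 of 12 cases (10 adjusted over the list alone, camera adjusted p = 0.000239, and 0.346 with an estimated correlation), with the malic enzyme Me1 at 138 ± 10.7 against 484 ± 36.0 CPM, Elovl5 at -1.07 ± 0.05 and Srebf1 at -0.99 ± 0.06. Stress response genes were lower in 11 of 15 cases and higher in 1 (11 and 1 adjusted over the list alone, camera adjusted p = 0.0429, and 0.764 with an estimated correlation), with Asns at -0.97 ± 0.08, Pdia4 at -0.51 ± 0.05, Calr at -0.62 ± 0.06 and Ddit3 at 1.13 ± 0.12. That list was lost without mono-cultured primary tumor replicate 2 (0.0603), while basal (0.0225) and glycolysis genes (0.0360) passed without primary tumor replicate 1 and neutrophil markers without early lesion replicate 1 (0.0396). Mki67 was higher in early lesion cells, at 233 ± 37.9 against 86.2 ± 33.4 CPM (1.43 ± 0.29, edgeR quasi-likelihood adjusted p = 0.00593). The G2/M (camera adjusted p = 0.536) and DNA replication lists (0.683) did not pass, with Cenpf at 1.15 ± 0.25, Pole at 0.89 ± 0.17 and Tyms at -0.35 ± 0.07. Tgfb1 was higher (0.38 ± 0.06), Tgfb2 (17.7 ± 0.572 against 30.5 ± 6.08 CPM, -0.78 ± 0.14) and Tgfb3 (-0.74 ± 0.18) were lower, and Tgfbr1 (0.19 ± 0.07), Cdkn1b (0.20 ± 0.05) and Cdh1 (0.15 ± 0.06) were higher. Nr2f1 (-1.24 ± 0.37), Gas1 (-1.37 ± 0.08) and Bhlhe41 (-0.50 ± 0.05) were lower, but the dormancy list did not pass (camera adjusted p = 0.920, 6 higher and 6 lower of 20, also adjusted over the list alone). Erbb2 (-0.24 ± 0.19), Tgfbr2 (-0.17 ± 0.08) and Tgfbr3 (0.26 ± 0.12) did not pass. TGF-β targets Id3 (1.66 ± 0.08) and Tgfbi (1.58 ± 0.10) were higher, Ltbp2 (-0.98 ± 0.08) and Inhbb (-0.66 ± 0.06) lower, Stat2 (1.02 ± 0.09) higher and Irf9 (-0.56 ± 0.07) lower, in lists that did not pass.

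The largest single differences were among ribosomal genes and pseudogenes. Rps12 had 215 ± 16.2 CPM in early lesion cells against 0.0133 CPM, a ratio of 19560 (95% counting interval 3510 to 772610). The pseudogenes Rps6-ps4 and Rps13-ps2 were at least 1070.1-fold and at least 610.4-fold higher against 3 counts over the group, and Eif4a-ps4 was at 6.30 ± 0.96. Rps16-ps3 was lower with a ratio of 2464 (442 to 97367) and Rpl7a-ps12 at -9.24 ± 0.35. Pseudogenes share reads with their parent genes, and whether both tables used 1 annotation and counting method is not known, so their values are uncertain. Of 151 pseudogenes differing by a log2 of at least 5, 42 were called the same way between the mono-cultured macrophages, as were 29 of 147 other genes. Rps12 had 55.2 ± 14.0 CPM in the primary tumor table's mono-cultured macrophages, so that table counted it, but a technical cause stays open. Dmbt1, a mucosal scavenger receptor, had a ratio of 2664 (478 to 105257), and Npy (-7.29 ± 0.85), Grip2 (-6.43 ± 0.88), A2m (-6.10 ± 0.38) and the cartilage protein Comp (-5.55 ± 0.55) were lower. In all 5100 genes were higher and 4958 lower of 14682 tested, and 74.0% had replicates that did not overlap. Relative to the mono-cultured macrophages of each experiment 4438 were higher and 4406 lower, 2744 and 2818 of them the same genes. Cdh1 (-1.49 ± 0.21) and Tgfbi (-2.39 ± 0.23) then passed in the other direction. Tgfb2 (1.47 ± 0.72), Tgfb3 (1.05 ± 1.11), Grip2 (2.50 ± 1.39) and Cdh2 (1.63 ± 0.69) changed sign without passing. Tgfbr1 lost its call without mono-cultured early lesion replicate 1 or 3 or primary tumor replicate 2 or 3, Cdh1 without any of the early lesion replicates or primary tumor replicate 2 or 3, Nr2f1 without early lesion replicate 2 or 3 or primary tumor replicate 2, and Fn1 without primary tumor replicate 3.

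Lists of endothelial, lymphocyte and lung epithelial markers, Wnt targets and the Notch pathway passed in the main fit of none of the comparisons that could test them, with smallest camera adjusted p-values of 0.235, 0.358, 0.293, 0.168 and 0.0778.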

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

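The interaction tests and the splits of the samples were planned, the fibroblast and library quality tests were written before their values were computed, and the other tests were chosen after the result was seen. The tumor cell responses differed in 15 genes higher and 6 lower by an interaction term. F5 (2.41), Chad (2.08), Rtp4 (1.99), Timp3 (1.04), Edil3 (0.96) and Cpt1a (0.88) responded more positively in early lesion cells, and Exoc3l4 (-1.35), Fam174b (-1.16), Dll1 (-0.67) and Tysnd1 (-0.44) more negatively. List medians differed for G2/M (-0.67), DNA replication (-0.70), TGF-β targets (0.17), fibroblast markers (0.73), neutrophil markers (1.16), interferon (0.45) and glycolysis and hypoxia genes (-0.24). Of 100 splits of the samples drawn, 4 called at least 21 genes, the real one included, and the highest other called 55. The 3 others kept the real primary tumor groups, so they still held that response.

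The macrophage responses differed in 720 genes higher and 783 lower. Cdkn1b (-0.66), Mki67 (1.22), the carry-over candidates Cdh1 (0.93) and Erbb2 (-2.04), Adam8 (3.84), Il7r (2.84), Hist2h3c2 (2.54), Itgam (2.53), Cxcl2 (2.41), Clec4e (2.30), Egln3 (-4.19), Fabp1 (-2.74), Bnip3 (-2.72), Rnase4 (-2.54), Apoc1 (-2.52) and Cyp2ab1 (-2.46) were the named genes. List medians differed for G2/M (0.79), DNA replication (0.78), alveolar macrophage markers (-0.42), inflammatory genes (0.74), glycolysis and hypoxia (-0.66), stress response (0.51) and mitochondrially encoded genes (-0.75).

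Mitochondrially encoded transcripts and Grip2 took most counts of the primary tumor experiment's macrophages, and 98.5% of the 1503 genes kept their call without them. TMM already scales such genes out (median change of 0.00411 in log2 against a median standard error of 0.187), so this decides nothing, and the lost depth stays open. After removal of a trend over transcript length 67.2% kept theirs, so a length effect could account for part, though glycolysis (-0.68), G2/M (0.74) and DNA replication medians (0.66) stayed. With 0 libraries of the other partner within 1 experiment, a library batch cannot be told apart from the partner.

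Epithelial transcripts in sorted macrophages could be tumor cell RNA at a single share. In the early lesion experiment 81.2% of 32 markers implied a share within 2-fold of the median of 0.542%, as that explanation needs. In the primary tumor experiment 54.5% of 33 did, which leaves it open. Cdh1 implied a share at least 16.3 times the other markers' median with early lesion cells, so a single share does not account for it, nor for Krt19, which implied 10.98% against 9.83% for Cdh1. With primary tumor cells Cdh1 implied 0.472% and Krt19 58.0%.

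Co-cultured early lesion replicate 1 stood apart, with a fibroblast marker mean of 6.21 log2 CPM against 4.48 to 5.40 in the other 5 libraries. A larger share of fibroblasts may add spread, since 2294 genes were called with that mean as a covariate against 76 without. Other lists as covariate gave a median of 157, but glycolysis and hypoxia genes gave 2551, so the gain is not particular to fibroblasts and the cause stays open. The library had a mitochondrially encoded share of 3.47% against 3.00 to 3.38% and a total of 29.3 M counts inside the range of the others, which does not settle whether it was degraded.

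The 3 against 3 comparisons allow 10 splits each, too few for a share under 0.05. The real split was the 1 with as many calls in each of these 4: 76 against 0 in the highest other for early lesion cells, 225 against 1 for primary tumor cells, 3403 against 0 for macrophages with primary tumor cells, and 10058 against 0 for stage.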

How the results depend on the processing

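The replicate block and the leave-one-out fits were planned, and the covariate, the fits without mitochondrially encoded genes and the list tests leaving out libraries were chosen after the result was seen. Of 6568 alternative values of 407 named results, called or not, 5985 kept their status, 427 lost a call, 150 gained 1 and 6 changed sign. Leaving out libraries ended 14 of 14 named calls in early lesion cells, 21 of 23 in primary tumor cells and 3 of 67 in macrophages with the latter. The cause was not tested unless stated.

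Counts are given as higher and lower. Without a filter they were 110.0 and 64 in early lesion cells, 192 and 274 in primary tumor cells, and 28 higher in the tumor difference. With DESeq2 they were 291 and 211, 358 and 423, and 203 and 126 in those 3. With a log2 change of at least 1, fewer by construction, they were 12 and 5, 20.0 and 19, 383 and 177 (macrophages with early lesion cells), 552 and 480.0 (with primary tumor cells), 5 and 3 (tumor difference), 256 and 272 (macrophage difference) and 2449 and 1002 (stage).

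With the replicate block, which the pairing check bears out for primary tumor cells only, counts were 303 and 182 in early lesion cells, 1430.0 and 1411 in primary tumor cells and 529 and 600.0 in the tumor difference. With all 4 groups in 1 fit they were 96 and 50 in early lesion cells, and 744 lower in macrophages with early lesion cells. With the fibroblast covariate they were 1077 and 1217 in early lesion cells. Without carry-over candidates, with fewer genes tested, they were 1035 and 901 in macrophages with primary tumor cells (536 and 438 at 2 times) and 422 and 424 in the macrophage difference.

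Leaving out 1 library gave 0 to 719 higher and 0 to 893 lower in early lesion cells, 4 to 75 and 0 to 87 in primary tumor cells, 887 to 1536 and 906 to 1431 in macrophages with early lesion cells, 1303 to 1756 and 1074 to 1637 with primary tumor cells, 7 to 113 and 2 to 71 in the tumor difference, 227 to 885 and 334 to 1005 in the macrophage difference, and 4560 to 5283 and 4430 to 5085 for stage. Where 1 library was left, it was assumed to vary like the other groups.

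Lists past the threshold were 6, 10, 16, 16, 7, 7 and 7 in the order early lesion cells, primary tumor cells, macrophages with each, tumor difference, macrophage difference and stage. With an estimated correlation they were 0 in all 7. With fry they were 0 in early lesion cells, 2 in primary tumor cells, 1 and 19 in macrophages with early lesion and primary tumor cells, 2 and 10 in the tumor and macrophage differences and 20.0 for stage. Without carry-over candidates, with fewer genes per list, they were 8 and 6 in macrophages with early lesion and primary tumor cells. Leaving out 1 library gave 3 to 8, 8 to 11, 16 to 18, 14 to 17, 4 to 10, 6 to 8 and 6 to 9 in the order above.

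Relative to mono-cultured macrophages the stage difference turned for Tgfb2 (1.47), Tgfb3 (1.05), Cdh1 (-1.49), Grip2 (2.50), Tgfbi (-2.39) and Cdh2 (1.63), with only Cdh1 and Tgfbi passing. The alveolar macrophage list in primary tumor cells turned without carry-over candidates (0.882), and the extracellular matrix list in early lesion cells without co-cultured replicate 1 (0.0338).

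Depth limits low genes in the 6 macrophage libraries of the primary tumor experiment.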

Other observations

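The genes here were chosen after seeing their values, and no test was run for them beyond those of the comparisons. Among genes of at least 10 CPM that were no carry-over candidates, 260 were higher and 243 lower in macrophages with both partners. The inhibitory Fc receptor Fcgr2b rose by 2.24 with early lesion and 2.50 with primary tumor cells, and the complement receptor C5ar1 by 1.22 and 2.27. The colony-stimulating factor receptor Csf1r changed by -0.93 and -1.53 and the oxidase subunit Cybb by -1.27 and -1.37.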
